A study of Mus musculus with 16 samples.

How the data were processed

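RNA from the livers of 16 mice, 4 in each of 4 groups, was measured by RNA sequencing. Per the labels' protocols the libraries were poly(A)-selected, strand-marked with dUTP and sequenced on DNBSEQ. The deposited files hold raw counts per Ensembl gene, 1 file per mouse, with no normalization. The submitters' processing notes name STAR 2.7.6, DESeq2 2.11.40.6 and 1.36.0 and the build GRCm39. The counting program, the annotation release and the strand setting are not given in the sources used here, so genes that overlap on opposite strands, and members of gene families with near-identical copies, carry an uncertainty that the counts do not resolve. Groups and replicate numbers were taken from the sample titles. The labels say that the libraries are from separate mice, and give no sequencing or library batch, so no comparison within batches could be made.

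Each file lists 55416 genes, of which 25938 had no count in any library. Symbols were added from a GENCODE M21 annotation of GRCm38, matched on the Ensembl identifier without its version. Of the identifiers 52083 (94.0%) matched, the 3333 others held 0.1% of the counts, and 135 identifiers shared a symbol with another. That annotation is of another build than the one the submitters name, so it was used for names alone and no coordinates are given, and some symbols are older ones. No entry lacked a gene identifier. Library totals ran from 18663498 to 28898229 counts, at which 3 counts, the upper limit that a count of 0 allows, correspond to 0.104 to 0.161 CPM (counting error only). All 24 pairs of replicates were compared by a chi-square test over genes with at least 20 counts in the pair. None was identical, and chi-square per gene ran from 14.52 to 118.98, so all libraries were kept as separate replicates.

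Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 14770, library sizes were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 16 libraries (12 residual degrees of freedom, common biological coefficient of variation 0.151). All 4 groups entered 1 fit so that each test shares the spread of 16 libraries. There were 5 tests per gene, pemafibrate against CMC in each adenovirus, Ad-FAT10 against Ad-CTRL in each treatment, and the interaction, which is the difference between the pemafibrate responses in Ad-FAT10 and Ad-CTRL livers. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and unless stated otherwise every adjusted p of a gene is from this test. The standard error of a gene's log2 change was taken as its absolute value divided by the square root of its quasi-likelihood F statistic. It therefore restates the test and is no separate measure of spread. Group levels are CPM after TMM scaling, as mean ± SD. Log2 CPM for scores and plots used a prior count of 2.

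Before the data were examined, 39 gene lists were fixed, from textbook knowledge of liver, PPARα, FAT10, stress, immunity and the cell types a liver holds. The lists hold 840 different genes, with up to 45 in each list, and several share genes, so they are not independent. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 39 lists within a comparison, and again with a correlation estimated from the list and with fry. Counts of genes in a list are given over all genes tested and adjusted over the list alone. The lists held with an estimated correlation were PPARα targets, the 3 fatty acid oxidation lists, ketogenesis and lipid droplet and uptake genes for pemafibrate in both adenoviruses, and cell cycle and p53 for Ad-FAT10 in both treatments. All other list calls were lost with it. With fry, 12 of 195 list tests lost a call and 6 gained one, so most calls lost with an estimated correlation were kept by fry. It asks if the genes of a list changed, and not if they changed more than other genes. The PPARα target score of a library is the mean log2 CPM of 44 measured targets. Scores were compared by exact two-sided permutation tests, over 70 assignments of 4 against 4 libraries (smallest p 0.0286) or 4900 for the interaction. For the interaction the adenovirus labels were exchanged within each treatment. An adenovirus difference in a score then widens the exchanged values, so an interaction p that does not pass leaves an interaction open.

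The genes named were set by a rule fixed before the data were examined. It took 16 genes of FAT10 and PPARα biology. For each comparison it took the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 1 log2 CPM, a standard symbol and, except for the interaction, no overlap between the groups. For each list and comparison it took up to 4 members with the smallest p. The text prints part of these, and some of them are not reported here.

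The model was tested on simulated counts drawn with the mean levels and dispersions of the real genes and the real library sizes, with no difference between groups other than those put in. Changes were put only into genes with a mean above 1 CPM, so recovery among genes of lower level was not tested. For pemafibrate in Ad-CTRL livers it recovered 50% of 100 genes changed 1.5-fold and 87% of 100 changed 2-fold among 14468 genes, with 3.5% of its calls false. For the interaction it recovered 17% and 65% among 14488 genes, with no false call.

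Alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, a filter at 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, a fit of only the libraries compared and the replicate number as a block. Further ones were a prior count of 0.5 for scores, scores without the Cyp4a and Acot genes or with each gene scaled to an SD of 1, and each library left out in turn. Alternatives added after the data were seen left out Ad-FAT10 Pema replicates 1 and 3 together, took the score relative to hepatocyte markers, and repeated the list tests without each library.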

Results

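Livers of 16 C57BL/6J mice were profiled by poly(A) RNA sequencing, 4 mice in each of 4 groups. At 8 weeks of age the mice had received, through the tail vein, either a control adenovirus (Ad-CTRL) or an adenovirus carrying FAT10 (Ad-FAT10). FAT10, the product of Ubd, is a ubiquitin-like modifier that directs proteins to the proteasome. After 4 days they were given the vehicle CMC or 1 mpk of pemafibrate (Pema), a selective agonist of the nuclear receptor PPARα, by gavage 18 h and 5 h before the liver was removed, with 5 h of fasting. The 2 adenoviruses and 2 treatments made 4 groups, given below with Ad-CTRL before Ad-FAT10 and CMC before Pema within each. The series title puts the question of which liver genes answered pemafibrate when FAT10 was overexpressed. Library totals ran from 18663498 to 28898229 counts, and 14770 genes had enough counts to be tested. The share of counts in mitochondrially encoded genes was 7.28% ± 1.20, 6.23% ± 0.781, 5.15% ± 0.503 and 4.46% ± 1.16 (SD, n = 4) in that order. The 10 most abundant genes held 19.3% ± 0.556 and 18.6% ± 0.549 of the counts in the Ad-CTRL groups and 15.1% ± 0.800 and 14.0% ± 1.05 in the Ad-FAT10 groups. The first principal component of log2 CPM (counts scaled to a common library total) held 39.2% of the variance and separated the adenoviruses, and the second held 31.8% and separated the treatments. On the third, with 4.7%, Ad-FAT10 Pema replicates 1 and 3 lay farthest apart, at 35.4 and -29.1.

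Ubd (ENSMUSG00000035186) was measured first, as the gene the adenovirus carried. Its level was 11.2 ± 3.05 CPM in Ad-CTRL CMC, 27.5 ± 14.5 in Ad-CTRL Pema, 236.6 ± 116 in Ad-FAT10 CMC and 459.8 ± 64.3 in Ad-FAT10 Pema (SD, n = 4). All 8 Ad-FAT10 libraries, the lowest at 110.5 CPM, lay above the highest Ad-CTRL library at 47.8 CPM. Ubd rose with Ad-FAT10 by 4.41 ± 0.39 on the log2 scale (SE, 21.2-fold, edgeR adjusted p = 4.8e-07) under CMC and by 4.06 ± 0.38 (16.7-fold, adjusted p = 8.1e-07) under pemafibrate. With pemafibrate Ubd rose by 1.30 ± 0.36 in Ad-CTRL livers (adjusted p = 0.00945, but 0.0524 without Ad-CTRL Pema replicate 2). In Ad-FAT10 livers it rose by 0.96 ± 0.33 (adjusted p = 0.0413), a call lost in 7 of 16 fits that each left out a library, the highest adjusted p being 0.12. The call was also lost by DESeq2 (adjusted p = 0.0562) and in edgeR with the replicate number as a block (adjusted p = 0.0591). Counts per gene did not separate transcripts of the vector from those of the mouse gene.

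**Figure D1:**
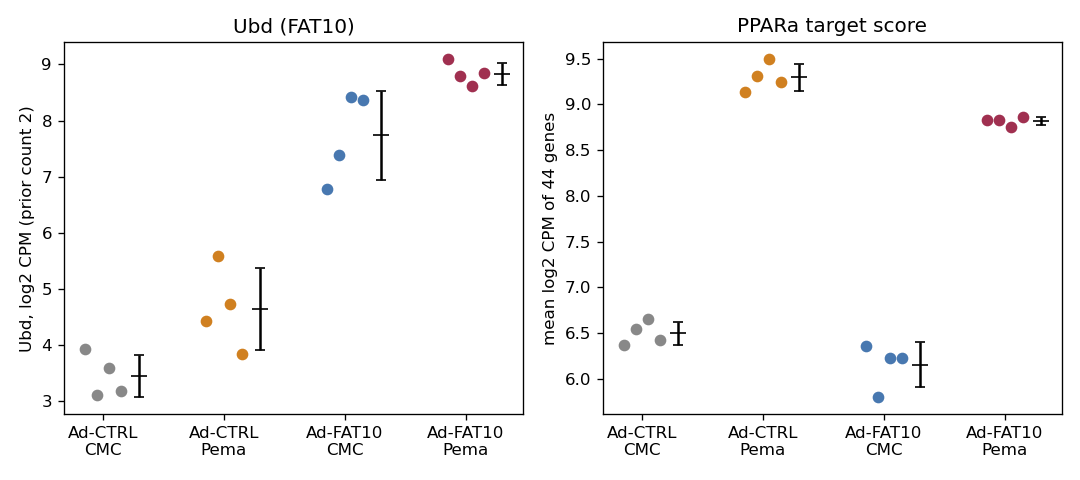
Left, log2 CPM of Ubd in each library by group; right, the PPARα target score, the mean log2 CPM of 44 target genes, in each library. Points are mice, horizontal ticks are group means and error bars are the SD (n = 4); the 8 Ad-FAT10 libraries lie above the Ad-CTRL libraries for Ubd, and the 8 pemafibrate libraries lie above the CMC libraries for the score.

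In Ad-CTRL livers, pemafibrate was compared with CMC to find the genes that answered the drug without FAT10 overexpression. Several genes of fatty acid oxidation were among the largest rises. Ehhadh, the peroxisomal bifunctional enzyme of beta-oxidation, rose from 255 ± 27.7 to 18720 ± 3057 CPM (SD, n = 4), a log2 change of 6.20 ± 0.29 (SE, edgeR adjusted p = 7.62e-11). Pdk4, the kinase that inactivates pyruvate dehydrogenase, rose from 3.28 ± 0.505 to 717 ± 164 CPM (7.77 ± 0.32, adjusted p = 2.88e-11). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 6.76 ± 0.30. Among the genes named by rule, the largest fitted log2 change was that of Cpne5, a copine, which went from 0.0750 ± 0.0269 to 24.2 ± 6.36 CPM. The lower level lies below the 0.104 to 0.161 CPM that 3 counts correspond to, so the size and rank of this change are uncertain. The fatty acid hydroxylases Cyp4a14 and Cyp4a10 rose by 8.00 ± 0.69 and 5.41 ± 0.40, although reads of the Cyp4a and Acot families can be split between close copies. In all 4523 genes changed, 2389 higher and 2134 lower, of which 602 and 575 by at least 2-fold.

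All 44 measured PPARα target genes rose (44 adjusted over the list alone), with a median log2 change of 2.26. The score of these genes was 6.5 ± 0.13 in CMC and 9.30 ± 0.15 in Pema (SD, n = 4). Its difference of 2.80 had an exact permutation p of 0.0286, two-sided, the smallest that 70 assignments can give (0.0357 after Benjamini-Hochberg adjustment over 5 tests), and all 4 Pema libraries were higher. Vnn1 rose by 3.43 ± 0.21, the hormone Fgf21 by 2.82 ± 0.46 and the lipase inhibitor Angptl4 by 1.25 ± 0.19. Smaller rises were seen for Ppara itself (ENSMUSG00000022383), at 0.60 ± 0.16 (adjusted p = 0.00791), and for Cpt1a, the entry enzyme of mitochondrial oxidation, at 0.52 ± 0.13 (adjusted p = 0.00604). Ppargc1a, a coactivator of PPARα, fell by 0.74 ± 0.19 (adjusted p = 0.00735).

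Of 33 peroxisomal oxidation genes 23 rose and 3 fell (23 and 3 adjusted over the list alone), with Crat at 3.20 and Pex11a at 2.56. Mitochondrial oxidation genes rose in 23 of 25 cases (24 adjusted over the list alone), among them the carnitine transporter Slc22a5 at 3.13 and Hadhb at 1.69. Among 12 omega-oxidation genes 8 rose and 1 fell (8 and 1 adjusted over the list alone). Ketogenesis genes rose in 6 of 7 cases (6 adjusted over the list alone), with Slc16a1, a transporter of ketone bodies and lactate, at 2.05 ± 0.11. In the lipid droplet and fatty acid uptake list 19 of 24 rose and 1 fell (19 and 2 adjusted over the list alone), with Plin2 at 2.69 ± 0.16, Cd36 at 2.80 ± 0.20, Fabp4 at 3.65 and Slc27a1 at 3.46. Fabp1 rose by 1.93 ± 0.17. The camera tests of these 6 lists, PPARα targets included, held with an estimated correlation between genes, the adjusted p being 0.000528, 0.00812, 0.000812, 0.0371, 0.019 and 0.000528 in the order given.

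The next 4 lists all lost their call with an estimated correlation. Of 34 proteasome genes 33 were higher (33 adjusted over the list alone), with a median log2 change of 0.53 and with Psmd11 at 0.82 and Psmd14 at 0.83 (camera adjusted p = 2.74e-15, adjusted p = 0.103 with an estimated correlation). In the heat shock list 11 of 14 rose (11 adjusted over the list alone), with the chaperones Hspd1 at 1.05 and Hsp90aa1 at 1.26 (adjusted p = 0.103 with an estimated correlation). Oxidative phosphorylation genes were higher in 17 of 40 cases (21 adjusted over the list alone), led by Ndufab1 at 1.54 (adjusted p = 0.731 with an estimated correlation). Triglyceride and fatty acid synthesis genes divided, 11 of 23 higher and 5 lower (11 and 5 adjusted over the list alone), with Mogat1 at 3.43 and Acacb at 1.72 (camera adjusted p = 0.0309, adjusted p = 0.769 with an estimated correlation). That list call was lost without Ad-CTRL CMC replicates 1 (camera adjusted p = 0.0966) or 2 (0.167), Ad-CTRL Pema replicate 2 (0.0525) or Ad-FAT10 CMC replicate 4 (0.0642).

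Some other lists held more lower than higher genes, and all lost their call with an estimated correlation. Amino acid catabolism and urea cycle genes fell in 19 of 29 cases and rose in 3 (21 and 3 adjusted over the list alone), with Gnmt at -1.54, Prodh at -2.01 and the urea cycle enzyme Asl at -1.33 (camera adjusted p = 2.91e-08, adjusted p = 0.179 with an estimated correlation). Bile acid genes fell in 8 of 19 cases and rose in 3 (10 and 3 adjusted over the list alone), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -2.26 and the transporter Slco1a4 at -2.80 (adjusted p = 0.406 with an estimated correlation). Acute phase genes fell in 14 of 32 cases and rose in 2 (18 and 2 adjusted over the list alone), with Serpina3m at -2.40 and Il6ra, the interleukin-6 receptor, at -1.22, while Il1rn rose by 2.49 (adjusted p = 0.523 with an estimated correlation). Type I interferon genes fell in 10 of 31 cases and rose in 1 (15 and 1 adjusted over the list alone), with Stat2 at -0.57 and Ifih1 at -0.70 (adjusted p = 0.769 with an estimated correlation). Cell cycle genes fell in 14 of 32 cases and rose in 2 (19 and 4 adjusted over the list alone), with Cdc20 at -1.41 (adjusted p = 0.769 with an estimated correlation), and the list was not called without Ad-CTRL Pema replicate 4 (camera adjusted p = 0.088). Lipoprotein genes divided, 3 of 23 higher and 5 lower (3 and 6 adjusted over the list alone), as did cholesterol genes, 3 of 24 higher and 3 lower (3 and 3 adjusted over the list alone), and neither list was called (camera adjusted p = 0.584 and 0.891). Single genes with large falls were the ion channel gene Hcn3 at -3.97 ± 0.42, Lrtm1 at -3.75 ± 0.48 and the steroid enzyme gene Hsd3b5 at -3.20 ± 0.61. Hepatocyte markers themselves fell in 10 of 20 cases and rose in 1 (10 and 1 adjusted over the list alone), with Ahsg at -1.06 and a median of -0.31 (camera adjusted p = 0.000988, adjusted p = 0.359 with an estimated correlation).

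In Ad-FAT10 livers the same drug comparison again put PPARα targets first. Of the 44 measured targets 43 rose (43 adjusted over the list alone), with a median log2 change of 2.28 (adjusted p = 3.94e-05 with an estimated correlation). Ehhadh rose from 268.8 ± 129 to 11040 ± 1474 CPM (SD, n = 4), a log2 change of 5.36 ± 0.28 (SE, edgeR adjusted p = 5.06e-10). Pdk4 rose from 7.57 ± 3.01 to 453 ± 125 CPM (5.91 ± 0.29, adjusted p = 2.8e-10). Fabp1 rose by 2.34 ± 0.17, Vnn1 by 2.80 ± 0.20, Angptl4 by 1.62 ± 0.19 and Fgf21 by 1.93 ± 0.41. Ppara (0.27 ± 0.16, adjusted p = 0.248) and Cpt1a (0.24 ± 0.13, adjusted p = 0.2) did not pass the test, though both did without Ad-FAT10 CMC replicate 1, at 0.45 and 0.37 (adjusted p = 0.0367 and 0.0416). The target score was 6.15 ± 0.24 in CMC and 8.82 ± 0.05 in Pema, a difference of 2.66 (exact permutation p = 0.0286, two-sided, 0.0357 adjusted), with all 4 Pema libraries higher. In all 3750 genes changed, 1898 higher and 1852 lower, of which 460 and 441 by at least 2-fold.

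The lipid oxidation lists held more higher than lower genes. Peroxisomal oxidation genes rose in 25 of 33 cases and fell in 2 (25 and 3 adjusted over the list alone). Mitochondrial oxidation genes rose in 22 of 25 (23 adjusted over the list alone), with Slc22a5 at 2.78 and Acadm, the medium-chain dehydrogenase, at 1.80. Omega-oxidation genes rose in 8 of 12 and fell in 1 (8 and 2 adjusted over the list alone). Ketogenesis genes rose in 6 of 7 (6 adjusted over the list alone). Lipid droplet and uptake genes rose in 18 of 24 and fell in 2 (19 and 2 adjusted over the list alone), with Plin2 at 2.59 ± 0.16 and Cd36 at 2.53 ± 0.20. The camera tests of these 5 lists held with an estimated correlation, at adjusted p = 0.00207, 0.000155, 0.0138, 0.00521 and 3.94e-05. Proteasome genes rose in 33 of 34 cases (33 adjusted over the list alone), with Psmd4 at 1.13 (camera adjusted p = 1.11e-13, adjusted p = 0.139 with an estimated correlation). Heat shock genes rose in 8 of 14 (9 adjusted over the list alone), with Hspd1 at 1.02 (adjusted p = 0.122 with an estimated correlation). Oxidative phosphorylation genes rose in 30 of 40 (34 adjusted over the list alone), with Ndufab1 at 1.22 and Cycs at 1.14 (adjusted p = 0.327 with an estimated correlation).

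All 9 measured neutrophil markers fell (9 adjusted over the list alone), with Csf3r at -0.86, Retnlg at -1.94 and the calprotectin subunit genes S100a8 and S100a9 at -1.99 and -1.63 (camera adjusted p = 0.000148, adjusted p = 0.228 with an estimated correlation). Acute phase genes fell in 19 of 32 cases (21 lower and 1 higher adjusted over the list alone), with Steap4 at -1.24, Crp at -0.72 and Il6ra at -1.03 (camera adjusted p = 6.05e-08, adjusted p = 0.193 with an estimated correlation). The largest fitted falls among the genes named by rule were Saa2 at -4.42 ± 0.87, the neutrophil protease gene Prtn3 at -3.80 ± 0.67, Saa1 at -3.78 ± 0.76 and Orm2 at -3.45 ± 0.62. Saa1 stood at 1761 ± 2478 CPM in CMC and 128.5 ± 38.5 CPM in Pema (SD, n = 4). The acute phase score of Ad-FAT10 CMC replicate 2 stood apart from the rest of its group, at 8.64 against 7.93, and without it Saa2 fell by 2.14, Saa1 by 2.02, Orm2 by 1.94 and Prtn3 by 2.85. Among NF-kB and cytokine genes 9 of 24 fell (10 adjusted over the list alone), with Tnfaip3 at -0.80 and Birc3 at -0.51 (adjusted p = 0.56 with an estimated correlation). Cell cycle genes fell in 21 of 32 cases (21 lower and 2 higher adjusted over the list alone), with Nusap1 at -1.01 and Cdc20 at -1.59 (adjusted p = 0.286 with an estimated correlation). Amino acid and urea cycle genes fell in 16 of 29 and rose in 1 (18 and 1 adjusted over the list alone), with Cps1 at -1.23 (adjusted p = 0.172 with an estimated correlation). Bile acid genes fell in 8 of 19 and rose in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.228 with an estimated correlation). Hepatocyte markers fell in 10 of 20 and rose in 1 (10 and 1 adjusted over the list alone), with a median of -0.34 (adjusted p = 0.228 with an estimated correlation).

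**Figure D2:**
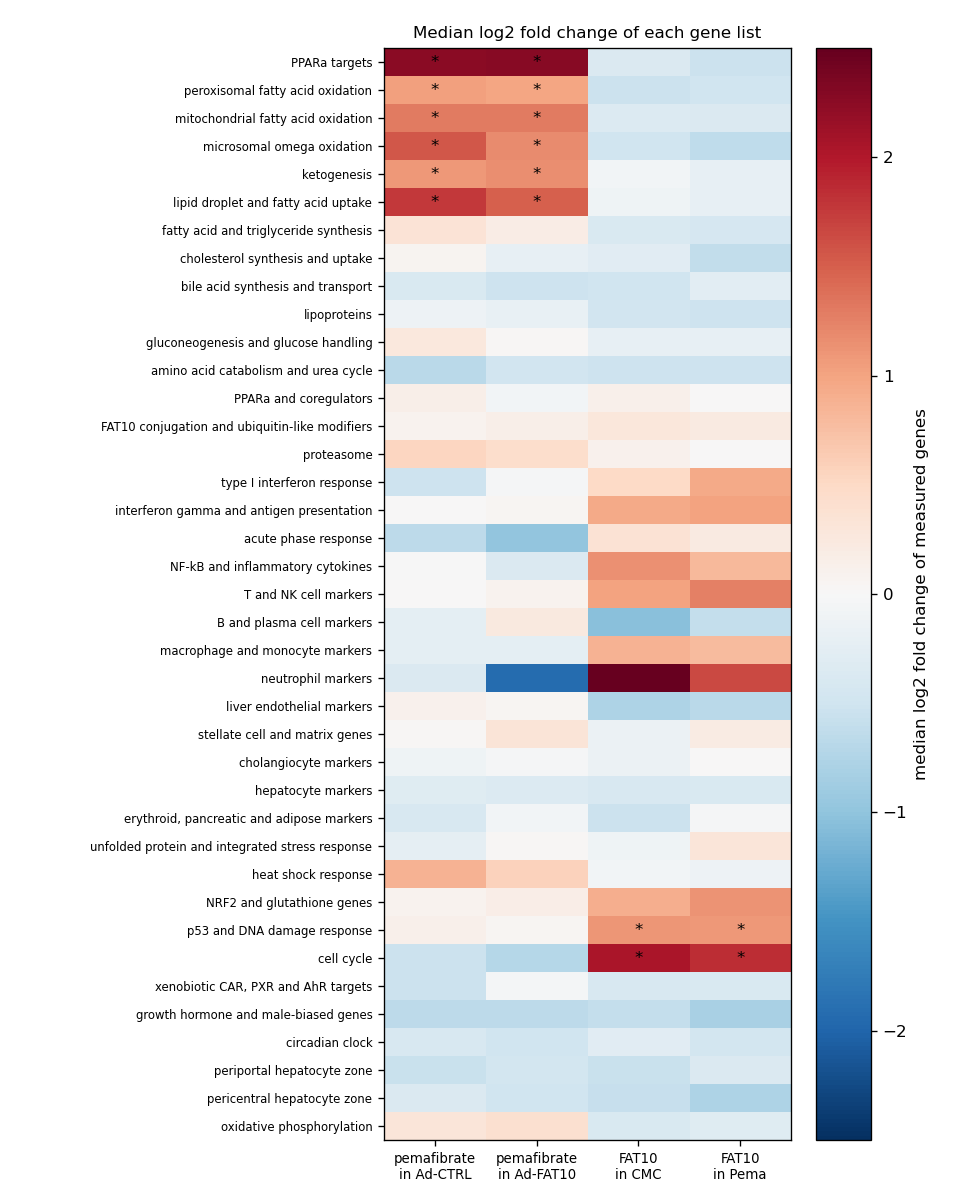
Median log2 fold change of the measured genes of each of 39 gene lists (vertical) in the 4 comparisons of groups (horizontal). Colour runs from blue (lower) to red (higher) on a scale that ends at 2.5 in each direction, and an asterisk marks an adjusted p under 0.05 in camera with an estimated correlation; asterisks stand at 6 lipid lists in both pemafibrate comparisons and at the p53 and cell cycle lists in both FAT10 comparisons.

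Across genes, the pemafibrate changes in Ad-CTRL and in Ad-FAT10 livers, which share no libraries, had a Pearson r of 0.811 and a Spearman rho of 0.686 over 14770 genes, which are not independent replicates. Of the genes changed in both, 1424 were higher in both and 1210 lower in both, against 307 and 268 for independent lists, and 7 had opposite directions.

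Under CMC, Ad-FAT10 livers were compared with Ad-CTRL livers to find what differed between the adenoviruses without the drug. The labels give all mice the same number of genome copies, but vector load in the liver and the response to the vector were not measured. In both adenovirus comparisons, and in the interaction, these cannot be told apart from FAT10 itself. Cell cycle and p53 target genes rose, and 5 of 6 markers of resident macrophages, picked once the falls had been seen, fell. In the cell cycle list 31 of 32 genes rose (31 adjusted over the list alone), with a median log2 change of 2.04 and the replication helicase genes Mcm6 at 2.96 ± 0.16 and Mcm5 at 2.34 ± 0.14 (edgeR adjusted p = 4.78e-09 and 1.31e-08). The list held with an estimated correlation (adjusted p = 0.0306). Of 20 p53 and DNA damage genes 18 rose and 2 fell (18 and 2 adjusted over the list alone), with Eda2r at 3.30 ± 0.23 and Tnfrsf10b at 3.60 ± 0.28 (adjusted p = 0.0349 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 4.78 ± 0.465 to 46.1 ± 18.4 CPM (SD, n = 4), by 3.27 ± 0.24 on the log2 scale. In all 6293 genes changed, 3316 higher and 2977 lower, of which 1213 and 492 by at least 2-fold.

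Single markers of infiltrating and resident cells moved apart, while no list of cell markers kept a call with an estimated correlation. By fry, which makes no comparison with other genes, neutrophil (adjusted p = 0.000171), T and NK cell (0.00149), B and plasma cell (0.00279) and endothelial markers (0.00652) were called. Macrophage and monocyte markers were not (fry adjusted p = 0.0569). All 9 neutrophil markers rose (9 adjusted over the list alone), with S100a8 at 3.16 ± 0.43 and Csf3r at 1.69 ± 0.16 (camera adjusted p = 4.49e-07, adjusted p = 0.281 with an estimated correlation). T and NK cell markers rose in 22 of 27 cases (23 adjusted over the list alone), with perforin, Prf1, at 2.21 and Cd3e at 1.85 (adjusted p = 0.353 with an estimated correlation). B and plasma cell markers fell in 8 of 12 (8 adjusted over the list alone), with Cd79a at -1.39 (adjusted p = 0.353 with an estimated correlation). Macrophage and monocyte markers divided, 14 of 22 higher and 5 lower (16 and 5 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.054). Its falls were in genes of resident liver macrophages, with Timd4 from 13.0 ± 1.21 to 1.14 ± 0.800 CPM (-3.55 ± 0.37, adjusted p = 1.74e-06), Cd163 at -3.28 ± 0.29, Vsig4 at -3.11 ± 0.31 and Clec4f at -2.89 ± 0.32. Of 2 further resident macrophage genes, Marco fell by 1.33 ± 0.46 (adjusted p = 0.0268) and Cd5l rose by 0.77 ± 0.21 (adjusted p = 0.00644). Mmp12, a macrophage elastase, rose by 3.97 ± 0.41. Liver endothelial markers fell in 11 of 15 cases (11 adjusted over the list alone), with Clec4g at -1.32 and Stab2 at -0.78 (adjusted p = 0.361 with an estimated correlation).

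No list of immune or stress genes below kept a call with an estimated correlation. By fry, the interferon gamma (adjusted p = 0.000788), NF-kB (0.000438), NRF2 (0.00165) and FAT10 conjugation lists (0.00155) were called. So were the acute phase (fry adjusted p = 0.0106) and type I interferon lists (0.0193), but not the proteasome list (0.125). Interferon gamma and antigen presentation genes rose in 33 of 36 cases (35 adjusted over the list alone), with Ciita, the activator of class II genes, at 1.71 and Socs1 at 1.99 (camera adjusted p = 2.06e-12, adjusted p = 0.353 with an estimated correlation). Type I interferon genes rose in 18 of 31 (19 higher and 1 lower adjusted over the list alone), with Zbp1 at 1.38 and Oas3 at 1.23 (adjusted p = 0.487 with an estimated correlation). NF-kB and cytokine genes rose in 19 of 24 (21 adjusted over the list alone), with Tnfaip3 at 1.70 and Icam1 at 1.62 (adjusted p = 0.337 with an estimated correlation). Acute phase genes rose in 15 of 32 and fell in 2 (15 and 2 adjusted over the list alone), with Saa3 at 2.74 and Cd14 at 2.36 (adjusted p = 0.433 with an estimated correlation). The list median was 0.37, and 0.196 without Ad-FAT10 CMC replicate 2, whose score stood apart from the rest of its group (8.64 against 7.93). Glutathione and NRF2 target genes rose in 17 of 23 (19 adjusted over the list alone), with the cystine transporter Slc7a11 at 3.93 and Gsta1 at 4.38 (adjusted p = 0.353 with an estimated correlation). The list of FAT10 conjugation and ubiquitin-like modifiers, which holds Ubd itself, rose in 10 of 24 cases and fell in 1 (10 and 1 adjusted over the list alone), with Ube2l6 at 0.61 and Herc6 at 0.77 (camera adjusted p = 0.0406, adjusted p = 0.353 with an estimated correlation). It was not called without Ad-CTRL CMC replicate 4 (camera adjusted p = 0.0693) or Ad-FAT10 CMC replicates 3 (0.0667) or 4 (0.0531). Proteasome genes were higher in 8 of 34 and lower in 1 (4 and 0 adjusted over the list alone), with Psmd1 at 0.47, and the list was not called (camera adjusted p = 0.268).

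Several lists of hepatocyte metabolism held more lower than higher genes, all without a call at an estimated correlation. PPARα targets fell in 24 of 44 cases and rose in 3 (27 and 4 adjusted over the list alone), with Fabp1 at -1.14 ± 0.16 and Cyp4a10 at -1.20 ± 0.34 (camera adjusted p = 1.08e-05, adjusted p = 0.353 with an estimated correlation). Pdk4 rose by 1.20 ± 0.28. The target score fell by 0.345 (exact permutation p = 0.0286, two-sided, 0.0357 adjusted), and p was 0.0571 without any 1 of the 4 Ad-CTRL CMC libraries or without Ad-FAT10 CMC replicate 2, where the difference was -0.25. Hepatocyte markers fell in 12 of 20 cases (14 lower and 1 higher adjusted over the list alone), with Rbp4 at -0.93 and Ttr at -0.77 and a median of -0.41 (adjusted p = 0.322 with an estimated correlation). Relative to these markers, an alternative chosen after seeing the data, the target score difference was 0.1, in the other direction (exact permutation p = 0.6). The marker score also changed with pemafibrate, by -0.368 in Ad-CTRL and -0.376 in Ad-FAT10 livers. The markers are thus not shown to be a fixed reference, and this difference is no measure corrected for hepatocyte share. Peroxisomal oxidation genes fell in 24 of 33 (25 lower and 1 higher adjusted over the list alone; adjusted p = 0.281 with an estimated correlation). Mitochondrial oxidation genes fell in 16 of 25 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.353 with an estimated correlation). Omega-oxidation genes fell in 6 of 12 and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.361 with an estimated correlation). Without 1 of 5 libraries that list was not called, at a camera adjusted p up to 0.0873 without Ad-CTRL CMC replicate 2. Lipoprotein genes fell in 14 of 23 (14 adjusted over the list alone), with Apoa2 at -1.41 and Apoa5 at -1.05 (adjusted p = 0.278 with an estimated correlation). Oxidative phosphorylation genes fell in 30 of 40 (30 adjusted over the list alone), with Ndufa2 at -0.91 (adjusted p = 0.361 with an estimated correlation). Amino acid and urea cycle genes fell in 21 of 29 and rose in 1 (22 and 1 adjusted over the list alone), with Hpd at -1.13 (adjusted p = 0.322 with an estimated correlation). Ketogenesis genes divided, 1 of 7 higher and 3 lower (2 and 3 adjusted over the list alone), with a median of -0.07 and a mean of 0.03, and the list was not called (camera adjusted p = 0.366). Lipid droplet and uptake genes divided too, 4 of 24 higher and 7 lower (4 and 7 adjusted over the list alone; camera adjusted p = 0.149).

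**Figure D3:**
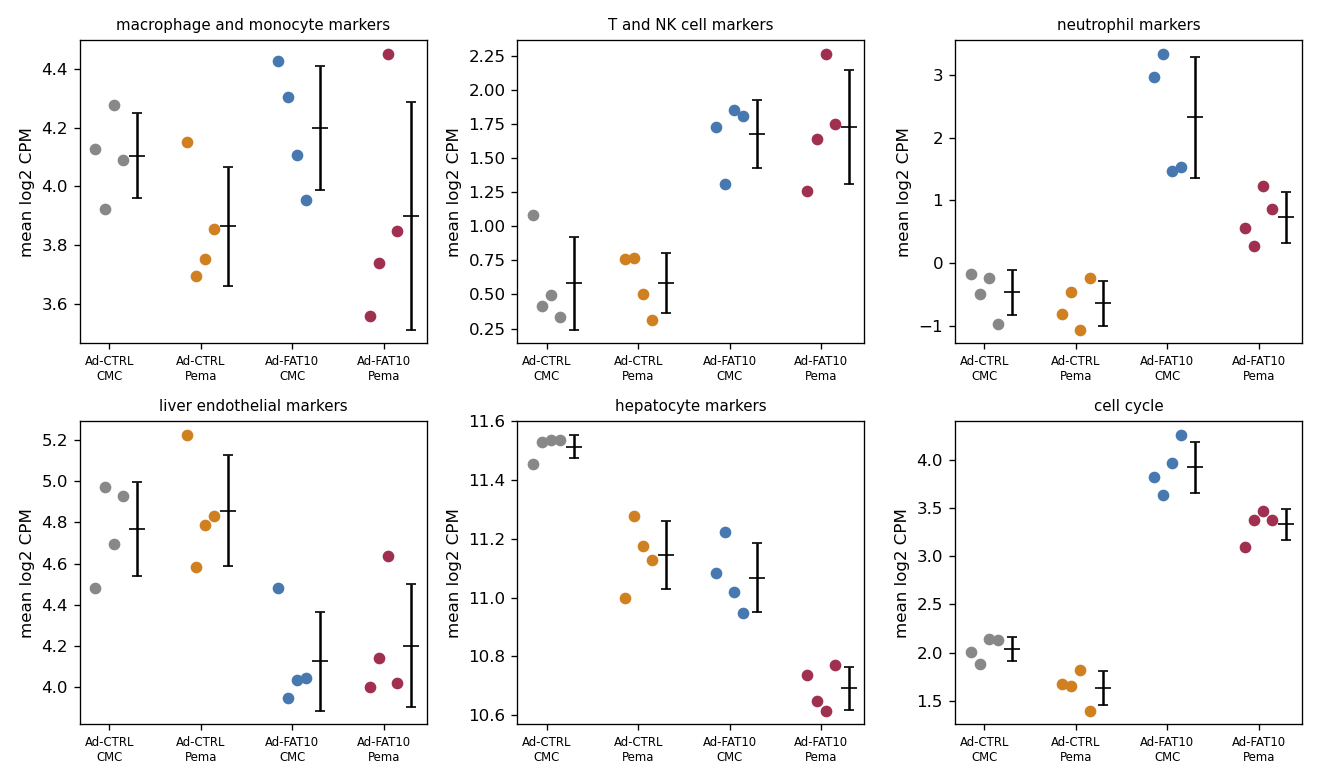
Mean log2 CPM of the measured genes of 6 lists in each library by group. Points are mice, horizontal ticks are group means and error bars are the SD (n = 4), and each panel has its own vertical axis, which does not start at 0; neutrophil, T and NK cell and cell cycle scores are higher in the Ad-FAT10 groups, and endothelial and hepatocyte scores are lower.

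The adenovirus comparison under pemafibrate gave 6160 changed genes, 3136 higher and 3024 lower, of which 1242 and 412 by at least 2-fold. Cell cycle genes rose in 31 of 32 cases (31 adjusted over the list alone), with Mcm6 at 2.64 ± 0.15 and Mcm2 at 2.03 ± 0.16 (adjusted p = 0.0397 with an estimated correlation). Of 20 p53 and DNA damage genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), with Phlda3 at 3.77 ± 0.24 (edgeR adjusted p = 3.93e-08) and Eda2r at 3.69 ± 0.24 (adjusted p = 0.0397 for the list with an estimated correlation). Cbr3, a carbonyl reductase, rose by 5.58 ± 0.66, and Saa3 by 3.47 ± 0.41. Cyp2a4 had a log2 change of 7.12 ± 1.28 (adjusted p = 0.000308), with reads that can be split with its close copy Cyp2a5. Of the same 6 resident macrophage genes 5 fell, Timd4 at -4.40 ± 0.40, Cd163 at -4.34 ± 0.31, Vsig4 at -3.66 ± 0.32, Clec4f at -3.19 ± 0.32 and Marco at -1.35 ± 0.46. The exception was Cd5l, which rose by 0.75 ± 0.21 (adjusted p = 0.00738). The macrophage and monocyte list had 16 of 22 genes higher and 5 lower (16 and 5 adjusted over the list alone; camera adjusted p = 0.0351, adjusted p = 0.564 with an estimated correlation). Without 1 of 7 libraries it was not called, at a camera adjusted p up to 0.194 without Ad-CTRL Pema replicate 2.

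None of the lists that follow kept a call with an estimated correlation. By fry all of them were called, at adjusted p up to 0.0461 (B and plasma cell markers), except the acute phase list (0.13). Type I interferon genes rose in 28 of 31 cases (28 adjusted over the list alone), with Oas1a at 1.64 and Oasl2 at 1.69 (camera adjusted p = 2.62e-11, adjusted p = 0.266 with an estimated correlation). Interferon gamma and antigen presentation genes rose in 32 of 36 (34 adjusted over the list alone), with H2-Ab1 at 1.37 (adjusted p = 0.266 with an estimated correlation). T and NK cell markers rose in 23 of 27 (23 adjusted over the list alone), with Trac at 1.55 (adjusted p = 0.266 with an estimated correlation). Neutrophil markers rose in 6 of 9 (7 adjusted over the list alone), with Csf3r at 1.10 and S100a9 at 1.86 (adjusted p = 0.337 with an estimated correlation). NF-kB and cytokine genes rose in 16 of 24 (16 adjusted over the list alone), with Vcam1 at 1.18 (adjusted p = 0.427 with an estimated correlation). NRF2 and glutathione genes rose in 17 of 23 (18 higher and 1 lower adjusted over the list alone), with Slc7a11 at 4.34 (adjusted p = 0.266 with an estimated correlation). B and plasma cell markers fell in 6 of 12 (6 adjusted over the list alone), with Ms4a1 at -1.32, and the list was not called (camera adjusted p = 0.134). Endothelial markers fell in 11 of 15 (12 adjusted over the list alone), with Clec4g at -1.41 (adjusted p = 0.41 with an estimated correlation). FAT10 conjugation and ubiquitin-like genes rose in 8 of 24 (8 adjusted over the list alone), with Usp18 at 1.00 (adjusted p = 0.266 with an estimated correlation). Acute phase genes rose in 9 of 32 and fell in 4 (9 and 4 adjusted over the list alone), with Lcn2 at 2.89 and no call for the list (camera adjusted p = 0.141).

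Several metabolic lists again held more lower than higher genes, all without a call at an estimated correlation. PPARα targets fell in 25 of 44 cases (27 lower and 1 higher adjusted over the list alone), with Retsat at -1.19, Vnn1 at -1.19 ± 0.19 and Cpt1a at -0.51 ± 0.13 (adjusted p = 0.266 with an estimated correlation). Ppara fell by 0.56 ± 0.16 (adjusted p = 0.00912) and Ehhadh fell by 0.76 ± 0.23 (adjusted p = 0.0145). Neither passed with Ad-FAT10 Pema replicates 1 and 3 left out, an alternative chosen after seeing the data, where Ppara changed by -0.49 (adjusted p = 0.0721) and Ehhadh by -0.67 (adjusted p = 0.0902), so the folds stayed near their size with 2 fewer libraries. The target score fell by 0.48 (exact permutation p = 0.0286, two-sided, 0.0357 adjusted), and relative to hepatocyte markers the difference was -0.027 (exact permutation p = 0.8). Hepatocyte markers fell in 14 of 20 cases (14 adjusted over the list alone), with Cyp2e1 at -1.25 and a median of -0.38 (adjusted p = 0.266 with an estimated correlation). Peroxisomal oxidation genes fell in 23 of 33 (24 lower and 1 higher adjusted over the list alone), with Phyh at -0.99 (adjusted p = 0.266 with an estimated correlation). Mitochondrial oxidation genes fell in 16 of 25 and rose in 1 (16 and 1 adjusted over the list alone), with Eci1 at -0.83 (adjusted p = 0.266 with an estimated correlation). Omega-oxidation genes fell in 6 of 12 and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.266 with an estimated correlation). Cholesterol synthesis and uptake genes fell in 9 of 24 (7 adjusted over the list alone), with Stard4 at -1.27 and Ebp at -0.83 (camera adjusted p = 0.00015, adjusted p = 0.472 with an estimated correlation). Lipoprotein genes fell in 16 of 23 and rose in 1 (16 and 1 adjusted over the list alone), with Apoa2 at -1.27 (adjusted p = 0.175 with an estimated correlation). Ketogenesis genes (1 of 7 higher and 3 lower, 1 and 3 adjusted over the list alone) and lipid droplet and uptake genes (3 of 24 higher and 9 lower, 3 and 9 adjusted over the list alone) were not called as lists (camera adjusted p = 0.371 and 0.204).

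Between the 2 adenovirus comparisons, which share no libraries, the log2 changes had a Pearson r of 0.834 and a Spearman rho of 0.798 across genes. Of the genes changed in both, 2379 were higher in both and 1987 lower in both, against 704 and 610 for independent lists, and 18 had opposite directions.

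The difference between the pemafibrate responses in Ad-FAT10 and Ad-CTRL livers was tested as an interaction, the question the design asks of FAT10 and the drug together. Il1rn, the interleukin-1 receptor antagonist, went from 10.2 ± 3.43 to 56.7 ± 5.05 CPM with pemafibrate in Ad-CTRL livers and from 39.2 ± 11.4 to 55.2 ± 11.1 CPM in Ad-FAT10 livers (SD, n = 4), an interaction of -2.0 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.0106). Pde7b, a cyclic AMP phosphodiesterase, went from 5.32 ± 0.594 to 18.7 ± 4.05 CPM in Ad-CTRL and from 4.68 ± 1.47 to 4.41 ± 0.532 CPM in Ad-FAT10 (-1.89 ± 0.27, adjusted p = 0.00856). Atp10d, a phospholipid flippase, rose in both, by 2.90 ± 0.15 and 1.66 ± 0.14 (interaction -1.25 ± 0.21, adjusted p = 0.0148). Pdk4 had an interaction of -1.86 ± 0.36 (adjusted p = 0.0492) and Rad51b, a recombination gene, one of -2.07 ± 0.38 (adjusted p = 0.0328). In all 23 genes differed, 4 with a higher and 19 with a lower log2 response in Ad-FAT10 livers, and 1591 had an unadjusted p under 0.05.

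Among the 11 interaction genes named by rule, the calls of Il1rn, Pde7b and Atp10d held without any single library, and those of Pdk4, Rad51b, Csf2rb (-1.02), Nek2 (-1.24), Prrg4 (-1.16), Rab4a (0.70), Map2k3 (0.67) and Madd (0.54) were each lost in 5 to 14 of 16 such fits. The number of genes was 93 without a filter on low counts, 120 by DESeq2 and 87 by limma-voom with quality weights, and from 11 to 36 when 1 library was left out. In the interaction, 1 of the 44 PPARα targets, Pdk4, was called (1 adjusted over the list alone), the list median was -0.07 and the list was not called (camera adjusted p = 0.321). The interaction of the target score was -0.135 (exact permutation p = 0.638 over 4900 assignments, two-sided), which does not show that the responses were alike. In simulated data, with changes put into genes with a mean above 1 CPM, this test recovered 65% of 2-fold differences and 17% of 1.5-fold differences.

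**Figure D4:**
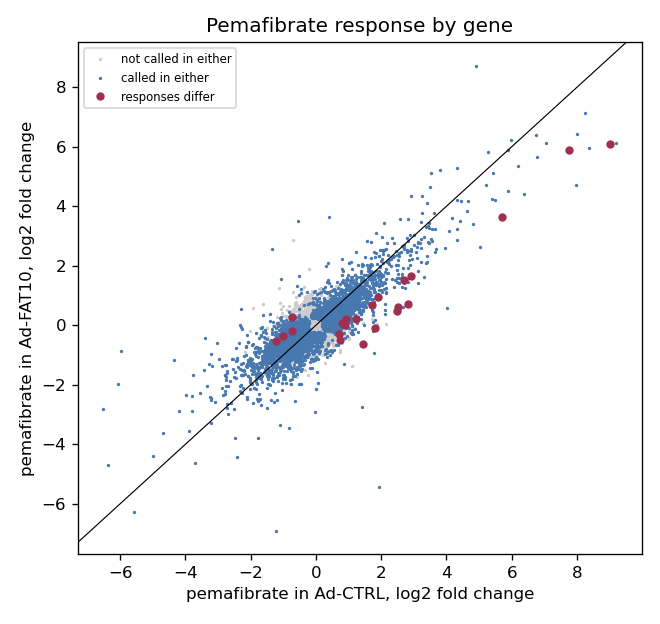
Log2 fold change of each of 14770 genes with pemafibrate in Ad-CTRL livers (horizontal) and in Ad-FAT10 livers (vertical), with the line of equal response. Grey genes were called in neither comparison, blue genes in at least 1, and the larger dark red points are the 23 genes whose responses differed, 19 of which lie below the line.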

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

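Of the tests in this part, the splits of the libraries, the macrophage tests, the neutrophil, acute phase and blood tests were chosen after the result was seen, and the 2 tests of a smaller pemafibrate response were set before their results were seen.

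Other splits of the same libraries were fitted to ask if chance alone gives as many genes. In each comparison of 2 groups the real split was the 1 of 35 with the most genes. It gave 4523 for pemafibrate in Ad-CTRL against at most 12 in another split, and 3750 against 119 for pemafibrate in Ad-FAT10. For FAT10 it gave 6293 against 1 in CMC and 6160 against 253 in Pema. A split that mixes the groups puts their difference into the spread, which lowers its own count. The size of the gap is thus no measure of chance, and a first place among 35 is the most these splits can show. For the difference between the pemafibrate responses, 3 of 100 splits gave at least the real 23 genes, a share under 0.05, and the highest other split gave 2430. A split with so many genes points to a structure of the samples, since exchanging adenovirus labels within 1 treatment moves the adenovirus difference into the interaction or into the spread, so this test is a lenient one.

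Among genes picked by their average response, 511 induced genes rose less in Ad-FAT10 livers, by a mean of 1.67 against 1.885 in Ad-CTRL (difference -0.215 ± 0.089, exact permutation p = 0.0388). The differences did not pass for 499 repressed genes, which changed by -1.302 and -1.492 (0.19 ± 0.143, exact permutation p = 0.192), or for the score of 44 PPARα targets (-0.135, exact permutation p = 0.638). An error of scaling between libraries would move both sets alike, but the difference for induced minus repressed genes was -0.405 ± 0.179 (exact permutation p = 0.04), which argues against it. The hepatocyte markers themselves differed by -0.008 ± 0.092 (exact permutation p = 0.974), but a lower share of hepatocyte RNA stays open, since the induced genes relative to these markers differed by -0.207 ± 0.138 (exact permutation p = 0.417), within 2 SE of 0. A weaker response to the drug in Ad-FAT10 livers may also be the source, and stays a hypothesis. Vector load and the response to the vector were not measured, so here too they cannot be told apart from FAT10 itself.

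The score of 6 markers of resident macrophages was lower in Ad-FAT10 livers, by -2.267 under CMC and -2.74 under pemafibrate, though 1 of them, Cd5l, rose by 0.77 and 0.75. These 6 were picked from their list once the falls had been seen, so no p is given for them. Dilution by other RNA would lower the other liver cell types alike, but the scores of 4 of their marker lists, fixed beforehand, did not follow. Their lowest score change was -0.656 ± 0.200 (SE), in endothelial cells under pemafibrate, and hepatocyte markers changed by -0.445 ± 0.062 and -0.454 ± 0.068. Each of the 4 lay above the macrophage score by 1.624 ± 0.289 or more. Because the 6 genes were picked for their falls, the choice itself favours such a gap. The gap shows that the 4 lists fell less than these genes, and is no independent test of dilution. A mislabelled library was argued against by Ubd, which in all 8 Ad-FAT10 libraries lay above every Ad-CTRL library. Unequal vector load or a response to the vector cannot be told apart from FAT10 itself, since 0 entries of the count table were other than mouse genes. Loss of resident cells, or lower expression of these genes within them, may each be the source. Counts from whole liver do not show which cells the Cd5l transcripts came from, so its rise does not separate them.

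With pemafibrate the neutrophil score changed by -1.594 in Ad-FAT10 livers (exact permutation p = 0.0286) and by -0.175 in Ad-CTRL (exact permutation p = 0.486), with an interaction of -1.419 ± 0.583 that was not called (exact permutation p = 0.285). Neutrophil markers rose with Ad-FAT10 by a median of 2.91 under CMC and 1.65 under pemafibrate. That difference widens the values under exchanged labels, so the interaction p leaves an interaction open. The acute phase score changed by -0.947 and -0.673 (exact permutation p = 0.0286 each, interaction -0.274 ± 0.273, p = 0.497). A single library as the source of the score changes was argued against. Without any 1 of the 8 they stayed at or beyond -1.257 for neutrophil and -0.77 for acute phase genes, both reached without Ad-FAT10 CMC replicate 2. The size of the largest single falls did rest on that library. Without it Saa2 went from -4.42 to -2.14, Saa1 from -3.78 to -2.02 and Orm2 from -3.45 to -1.94. Less blood left in the liver was not seen in 4 haemoglobin genes, whose score changed by 0.092 (exact permutation p = 0.771). However, 2 other erythroid genes fell, Alas2 by 0.95 and Slc4a1 by 1.53 (adjusted p = 0.0141, but -0.86 and adjusted p = 0.123 without Ad-FAT10 CMC replicate 2). The erythroid genes divided, and haemoglobin does not show how many neutrophils the blood held, so blood left in the liver stays open. Fewer neutrophils in the liver, or lower expression within them, may each be the source, and no test here separates them.

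Single libraries stood apart from the other 3 of their group by Dixon's ratio, above its critical value, in 10 of 236 groups tested, where chance gives about 1 in 20, or 11.8. These were Ppara in Ad-CTRL CMC replicate 3 (ratio 0.891, 7.26 against a mean of 6.88 log2 CPM), Ehhadh in Ad-FAT10 Pema replicate 1 (0.971, 13.11 against 13.52) and Fabp1 in Ad-CTRL Pema replicate 1 (0.885, 14.08 against 13.82). Among list scores they were lipid droplet genes in Ad-CTRL CMC replicate 2 (0.881, 5.45 against 5.53), bile acid genes in Ad-FAT10 Pema replicate 3 (0.842, 6.05 against 6.44) and gluconeogenesis genes in Ad-FAT10 Pema replicate 4 (0.833, 6.83 against 6.6). They were also acute phase genes in Ad-FAT10 CMC replicate 2 (0.879, 8.64 against 7.93) and hepatocyte markers in Ad-CTRL CMC replicate 1 (0.92, 11.45 against 11.53). Of library measures, the total of Ad-FAT10 CMC replicate 1 (0.875, 19.86 against 24.41 megacounts) and the share of the top 10 genes in Ad-FAT10 CMC replicate 2 (0.886, 16.28% against 14.69%) stood apart.

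The pemafibrate responses in Ad-FAT10 and Ad-CTRL differed, by the interaction test, for Rab4a (0.70), Map2k3 (0.67), Madd (0.54), Rad51b (-2.07), Il1rn (-2.0), Pde7b (-1.89), Pdk4 (-1.86), Atp10d (-1.25), Nek2 (-1.24), Prrg4 (-1.16) and Csf2rb (-1.02). By list median they differed at the preset correlation for type I interferon genes (0.47, camera adjusted p = 2.85e-07), neutrophil markers (-1.05, 0.000186), NF-kB genes (-0.30, 0.000201), cholesterol genes (-0.25, 0.00918), PPARα and its coregulators (-0.19, 0.0257) and unfolded protein response genes (0.27, 0.0366). All 6 list calls were lost, at adjusted p = 0.948 with an estimated correlation. With 1 library left out the interferon call held. The neutrophil call held too, with a median of -1.72 without Ad-CTRL CMC replicate 1, -1.68 without Ad-CTRL Pema replicate 3, -1.76 without Ad-FAT10 CMC replicate 3 or 4 and -1.625 without Ad-FAT10 Pema replicate 1. So did the NF-kB call, at -0.49 without Ad-CTRL CMC replicate 1 and -0.16 without Ad-FAT10 CMC replicate 3. The cholesterol call was lost without Ad-CTRL CMC replicate 1 (-0.22, camera adjusted p = 0.0745) or 2 (-0.14, 0.185), Ad-CTRL Pema replicate 2 (-0.165, 0.11), Ad-FAT10 CMC replicate 2 (-0.15, 0.0582) or Ad-FAT10 Pema replicate 3 (-0.14, 0.228). Its median was -0.39 without Ad-CTRL CMC replicate 3 and -0.415 without Ad-FAT10 Pema replicate 2. The call of PPARα and its coregulators was lost without any 1 of 6 libraries, with the smallest median without Ad-CTRL Pema replicate 3 (-0.09, 0.0922), and the median was -0.30 without Ad-CTRL Pema replicate 1. The unfolded protein response call was lost without any 1 of 7, with the smallest median without Ad-FAT10 Pema replicate 1 (0.105, 0.182).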

How the results depend on the processing

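The alternatives were chosen before the data were examined, except 3 chosen after seeing the data, the omission of Ad-FAT10 Pema replicates 1 and 3, the score relative to hepatocyte markers and the list tests without each library. Where a value moved, the cause was not tested.

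The 4 counts of changed genes between 2 groups moved by less than 1.5 times under every alternative run, and with each library left out ran from 3753 to 4791 and from 2988 to 3863 for pemafibrate in Ad-CTRL and Ad-FAT10, and from 5335 to 6616 and from 5231 to 6427 for FAT10 in CMC and Pema. The count of 23 genes with different responses was 93 (28 higher, 65 lower) without a filter, 120 (39 and 81) by DESeq2, 87 (22 and 65) by limma-voom with quality weights and 17 without Ad-FAT10 Pema replicates 1 and 3. With 1 library left out it ran from 11 to 36, with 15, 14 and 14 without Ad-CTRL CMC replicates 1, 3 and 4, 36, 11 and 11 without Ad-CTRL Pema replicates 1, 3 and 4, 12 without Ad-FAT10 CMC replicate 3, and 14 and 13 without Ad-FAT10 Pema replicates 2 and 4. Quality weights ran from 0.43 (Ad-FAT10 Pema replicate 1) to 2.53 (Ad-FAT10 Pema replicate 2), and DESeq2 gave 2580 genes no adjusted p in the interaction.

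The target score differences ran from 2.735 to 2.855, from 2.562 to 2.734, from -0.414 to -0.25 and from -0.535 to -0.415 with 1 library left out, and the interaction from -0.215 to -0.065. For FAT10 in CMC the exact permutation p was 0.0571 without Ad-CTRL CMC replicates 1 (-0.389), 2 (-0.328), 3 (-0.294) or 4 (-0.371), or Ad-FAT10 CMC replicate 2 (-0.25). Relative to hepatocyte markers, which are not shown to be a fixed reference, that difference reversed, to 0.1 (exact permutation p = 0.6). For FAT10 in Pema it was -0.027 (exact permutation p = 0.8).

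The replicate numbers did not pair the libraries, with correlations from -0.172 to 0.131 between groups. With the number as a block, the model kept 4249, 3484, 5961, 5853 and 14 of the genes called. Its 16 interaction genes were 0 higher and 16 lower, so all 4 higher calls were lost, and among named genes those of Rab4a (adjusted p = 0.0836), Map2k3 (0.0589), Madd (0.0622), Rad51b (0.0575), Nek2 (0.057) and Prrg4 (0.0622). Outside the interaction, the calls lost included that of Ubd with pemafibrate in Ad-FAT10 livers (adjusted p = 0.0591). The score differences 2.799, 2.665, -0.345 and -0.48 had an exact permutation p of 0.125, the smallest 4 pairs can give.

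Of 17380 values of named genes under the alternatives, 16996 kept their call or its absence, 291 lost a call, 93 gained a call and 0 reversed. Of 195 list tests, 84 lost a call with an estimated correlation, and with fry 12 lost and 6 gained a call.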

Other observations

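Of the lists outside the report's main themes, circadian clock genes fell in 10 of 19 cases and rose in 1 with pemafibrate in Ad-CTRL (11 and 1 adjusted over the list alone). They fell in 11 and rose in 1 in Ad-FAT10 (13 and 1 adjusted over the list alone), with Per2, a clock repressor, at -0.86 and -0.72 (adjusted p = 0.406 and 0.139 with an estimated correlation). With FAT10 they fell in 9 in CMC (9 adjusted over the list alone) and in 12, with 1 higher, in Pema (13 and 1 adjusted over the list alone), with Dbp at -0.83 and -0.86 (adjusted p = 0.353 and 0.266 with an estimated correlation). Growth hormone and male-biased genes fell in 10, 13, 10 and 13 of 20 cases in the order pemafibrate in Ad-CTRL, pemafibrate in Ad-FAT10, FAT10 in CMC and FAT10 in Pema (14, 14, 10 and 13 adjusted over the list alone), and rose in 3, 2, 0 and 0 (3, 3, 0 and 0 adjusted over the list alone). Ghr, the growth hormone receptor, fell by 0.88 and 0.97 with FAT10 (adjusted p for the list = 0.731, 0.327, 0.353 and 0.266 with an estimated correlation).

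Genes of the pericentral zone of the liver lobule fell in 9, 10, 13 and 14 of 20 cases and rose in 3, 2, 0 and 1 in the same order. Adjusted over the list alone the counts were 9, 11, 14 and 15 lower and 3, 2, 0 and 1 higher, with Lect2 at -0.94, -0.94, -1.03 and -1.03 (adjusted p = 0.769, 0.444, 0.337 and 0.266 with an estimated correlation). Periportal genes fell in 11, 9, 11 and 9 of 19 and rose in 1, 1, 5 and 5. Adjusted over the list alone the counts were 12, 11, 12 and 10 lower and 1, 1, 5 and 5 higher, with Rnase4 at -1.29 and -1.31 with pemafibrate and Cdh1 at 0.76 and 1.08 with FAT10 (adjusted p = 0.103, 0.139, 0.361 and 0.564 with an estimated correlation). Xenobiotic genes fell in 10, 6, 10 and 9 of 22 and rose in 5, 6, 2 and 6. The counts adjusted over the list alone were 10, 6, 10 and 11 lower and 6, 7, 2 and 6 higher, with Nr1i3, the receptor CAR, at 0.80 with pemafibrate in Ad-FAT10 and -1.73 and -0.95 with FAT10 (adjusted p = 0.882, 0.915, 0.353 and 0.564 with an estimated correlation).

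Other lists had no call at the preset correlation in most comparisons. Glucose handling genes rose in 6, 3, 3 and 1 of 21 and fell in 8, 8, 5 and 8. Adjusted over the list alone the counts were 10, 3, 3 and 1 higher and 8, 8, 4 and 8 lower, with Gpd1 at 1.80 and 1.40 with pemafibrate and a call in FAT10 in Pema (camera adjusted p = 0.03, adjusted p = 0.471 with an estimated correlation). That call was lost without Ad-CTRL Pema replicates 2 (camera adjusted p = 0.0543) or 3 (0.072), or without Ad-FAT10 Pema replicate 1 (0.055). PPARα and its coregulators rose in 6, 3, 4 and 2 of 21 and fell in 3, 5, 0 and 5. Adjusted over the list alone the counts were 7, 3, 2 and 1 higher and 3, 5, 0 and 1 lower, with Nrip1 at 1.08 with pemafibrate in Ad-CTRL. Unfolded protein response genes rose in 2, 4, 2 and 6 of 26 and fell in 6, 4, 5 and 5. The counts adjusted over the list alone were 2, 5, 2 and 8 higher and 6, 4, 4 and 5 lower, with Herpud1 at -0.43, -0.74, -0.44 and -0.75. Stellate cell and matrix genes rose in 1, 3, 4 and 9 of 22 and fell in 0, 0, 6 and 6. The counts adjusted over the list alone were 1, 2, 4 and 10 higher and 0, 0, 7 and 6 lower, with Col4a1 at 0.95, 0.92, 1.13 and 1.09. Among 10 cholangiocyte markers Krt23, a keratin, rose by 4.63 and 3.83 with pemafibrate, while the list median was -0.10 and -0.02 and its mean 0.33 and 0.27. Of 19 erythroid, pancreatic and adipose markers 8 were measured, with Alas2, of heme synthesis, at -0.95 with pemafibrate in Ad-FAT10 and -0.88 and -1.37 with FAT10, and the list had no call.

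The median and mean of a list differed in sign in further cases, among them heat shock genes in FAT10 in CMC (median -0.06, mean 0.07), stellate genes in FAT10 in CMC (-0.15 and 0.09), ketogenesis genes in FAT10 in CMC (-0.07 and 0.03), cholesterol genes in pemafibrate in Ad-CTRL (0.07 and -0.01) and glucose handling genes in pemafibrate in Ad-FAT10 (0.02 and -0.09). The same held for xenobiotic genes in FAT10 in Pema (-0.39 and 0.13) and in pemafibrate in Ad-FAT10 (-0.04 and 0.11).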
